A study of Mus musculus with 7 samples.

How the data were processed

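The study compared mesenteric artery of 3 male mice with smooth muscle expression of dominant-negative P467L PPARγ and 4 non-transgenic littermates. Per the labels' protocols, RNA was extracted with Trizol and a column kit, about 50 ng was amplified in a 2-step procedure and labelled with biotin, and each RNA, from 1 mouse and not pooled, was hybridised to an Affymetrix mouse exon 1.0 ST array. This array places probes in exons along the gene, and a transcript cluster is a set of probes summarised together, typically for 1 gene. The deposited values are on the log2 scale with 2 decimals, 1 per array and row, each row taken here as a transcript cluster. Per the submitters' processing notes they were made with Affymetrix Power Tools and RMA on the mm9 build. Versions, the probe set level and background options are not given in the sources used here. As usually run, RMA corrects background, makes the distributions of arrays alike by quantile normalization and summarises probes by median polish. Differences of dim probes are shrunk in such values. Median polish with few arrays returns ties: 4671 rows held 1 value on 4 or more arrays and 283 on all 7. Detection calls were not used here, so a low value has no stated background limit.

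Rows were named through the platform annotation that accompanied the values. Of 23332 rows, 14996 had 1 gene symbol, 1019 had several and 7317 had none, and rows with several or none were tested but not named. No row was left out as a control, so control rows may be among those without a symbol. Entrez identifiers of 14941 rows were found in the RefSeq gene table of the GRCm38 assembly, which updated 0 symbols. That table was used only for names and for which genes neighbour each other, since the submitters name mm9. In the named rows 14860 genes were distinct, and 135 had more than 1 row. In lists such a gene was represented by the row with the highest mean over all arrays. Beside the 7 sample columns, 0 columns of per-sample values were present.

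All rows were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no filter on dim rows, no covariate), with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. Intervals are 95% intervals from the moderated fit. The moderation borrowed little across rows, with 1.01 prior degrees of freedom, and the median standard error of a difference was 0.117 on the log2 scale. Differences are P467L minus non-transgenic means and folds are 2 to the power of that difference. Before the data were examined, the test, 33 gene lists with 833 distinct genes (636 measured), the alternatives and the rule for named genes were fixed. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the 31 lists tested, with an estimated correlation and fry as alternatives. A list's score is the mean over its genes of the log2 deviation from the gene's mean over all arrays, compared between groups by an exact two-sided permutation test over the 35 splits. No list was chosen on these samples. The result of 1 of the lists tested is not reported here.

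Named genes are 8 genes fixed in advance (Pparg, Myh11, Rhobtb1, Cul3, Fabp4, Cd36, Rgs5 and Arntl) and up to 10 per direction with the largest difference among those passing. As 0 passed, these were filled with the 10 of smallest p in each direction, which do not pass. Up to 3 members of smallest p per list complete the rule, and rows need exactly 1 symbol. Acta2, Tagln, Adipoq and Tyrobp were named after their values were seen.

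The fit was tested on simulated data for this comparison, with 200 of 23332 rows changed and row means and spreads taken from the arrays. It called 30 of 67 rows changed by 0.5 (44.8%), 51 of 67 changed by 1 (76.1%) and 65 of 66 changed by 2 (98.5%), with 15 false calls, and it made 0 calls where nothing was changed. In that simulation rows vary independently, and 5.37% of unchanged rows had an unadjusted p under 0.05. The spread estimated for each row was taken as its true spread. Rows with ties therefore enter with small spreads, and the rates of called rows may be too high. The rates hold for 200 changed rows, since the Benjamini-Hochberg cutoff is stricter when fewer rows change. In the arrays themselves a row with a difference of -3.30 was not called (limma, adjusted p = 0.709).

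The alternatives were a further quantile normalization, centring on array medians, leaving out the lowest 25% or 50% of rows, trended robust moderation, array weights, the replicate number as a block, the adipocyte score as a covariate, only rows with 1 symbol, and each array left out in turn. The adipocyte score used as a covariate is the mean over the markers of values centred and scaled to each gene's SD. It differs from the list score, which is not scaled. Chosen after seeing the data were leaving out rows tied on 4 or more arrays and the first principal component of the residuals as a covariate. The array weights were 3.54, 0.46 and 0.33 for P467L replicates 1, 2 and 3, and from 0.75 to 1.69 for the non-transgenic arrays. With array weights the P467L mean therefore rests mostly on replicate 1. Scan dates and other batch information were not used here. Figures were drawn with matplotlib 3.10.9.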

Results

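Gene expression was measured in mesenteric artery, the small resistance-type vessel bed that feeds the intestine, from 3 male mice carrying a dominant-negative form of human PPARγ (P467L) in smooth muscle and from 4 non-transgenic littermates. PPARγ is a nuclear receptor that switches on genes of lipid uptake and storage, and the P467L protein interferes with it. The transgene was placed under the promoter of smooth muscle myosin heavy chain, so the design asks what blocking PPARγ in smooth muscle does to the transcripts of the vessel. Each array held the RNA of 1 mouse, and the 7 arrays reported 23332 rows, each taken as a transcript cluster, with 1 log2 value per mouse. Array medians lay between 6.29 and 6.34, and single values between 1.58 and 13.9. Upper quartiles differed more, from 7.10 in P467L replicate 3 to 7.29 in non-transgenic replicate 1. Between any pair of arrays, Pearson's r across rows was 0.954 to 0.979, where rows are not independent replicates. On the first principal component, which held 33.7% of the variance and has an arbitrary sign, the P467L arrays stood apart from each other: replicate 3 was at 42.9 and replicate 2 at -31.2, the ends of the range, and the other 5 arrays lay between -27.4 and 17.6. The number of arrays limits the precision of every value given here.

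The transgene left no visible trace in the row of Pparg. Its log2 value was 6.78 ± 0.30 (SD, n = 4) in non-transgenic and 6.66 ± 0.16 (SD, n = 3) in transgenic artery, a difference of -0.12 with a 95% interval from -0.55 to 0.32 (limma, adjusted p = 1). The probes were made for the mouse gene, and whether they bind the human transgene is not known here, so the row does not check the genotype labels. Without non-transgenic replicate 1 the difference was 0.027. Myh11, whose promoter drove the transgene, differed by -0.093, more than the SDs of 0.063 and 0.067 within the groups (limma, adjusted p = 1). Its 95% interval, from -0.22 to 0.034, included 0, and the groups overlapped. Cul3, a ubiquitin ligase scaffold, differed by -0.022, less than its SDs of 0.18 and 0.20. Rhobtb1, a Cullin-3 partner chosen in advance, is not named in the probe annotation used here and was not analysed here.

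No single gene separated the genotypes after correction for the number of rows tested. At an adjusted p of 0.05, limma called 0 rows higher and 0 rows lower in P467L artery, and the smallest adjusted p was 0.709. At an unadjusted p of 0.05 it listed 724 rows (361 higher and 363 lower), or 3.10% of all rows, against 1167 that chance would give. In 600 rows (2.57%) the values of the 2 groups did not overlap, against 5.71% by chance. With 3 against 4 mice the smallest two-sided exact permutation p is 0.0571, so no single value could pass 0.05 in that test.

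The 10 named genes with the smallest p among those with higher means in P467L artery did not pass, and their differences ran from 0.24 to 1.10 on the log2 scale. Casq1, the calcium-binding calsequestrin of the sarcoplasmic reticulum, had the smallest p of these, at 8.42 ± 0.17 (SD, n = 3) in P467L against 7.32 ± 0.23 (SD, n = 4) in non-transgenic artery. This is a 2.14-fold higher mean, with a standard error of 0.15 on the log2 scale (limma, adjusted p = 0.863). Borcs7, part of a complex that positions lysosomes, had a 2.08-fold higher mean. Lpar4, a receptor for lysophosphatidic acid, differed by 0.64, and Dtx3l, a ubiquitin ligase, by 0.69. Vldlr, the very low density lipoprotein receptor, differed by 0.31, and the prohormone-processing enzyme Cpe by 0.24. The remaining genes were Ppp1r3f (0.44), Sprr2b (0.91), the olfactory receptor gene Olfr550 (0.72) and Hmgn3 (0.40). Sprr2b (2.735 in non-transgenic and 3.64 in P467L artery) and Olfr550 (4.22 and 4.94) were dim. Both lay below the lower quartile of every array, 5.26 to 5.29.

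The 10 named genes with the smallest p among those with lower means did not pass either. Cpt1a, which brings long-chain fatty acids into mitochondria, led them with 7.577 ± 0.081 (SD, n = 3) in P467L against 7.995 ± 0.058 (SD, n = 4) in non-transgenic artery. Its mean was 1.34-fold lower, a difference of -0.42 with a standard error of 0.054 (limma, adjusted p = 0.822). Kcne4, a subunit of potassium channels, had a 1.61-fold lower mean, and Higd1b, a mitochondrial gene known as a pericyte marker, a 1.79-fold lower one. P2rx1, the ATP-gated channel of arterial muscle, differed by -0.55, and Sync, which binds desmin filaments, by -0.38. Timp4, an inhibitor of matrix metalloproteinases, had a 1.71-fold lower mean, and Cpxm2 differed by -0.49. Ppt1, a lysosomal thioesterase, differed by -0.23, Olfr11 by -0.50 and Tnp1 by -0.42. Rgs5, a brake on G protein signalling that is abundant in pericytes and arterial muscle, had been chosen in advance. Its 2 rows had 2.83-fold and 2.08-fold lower means in P467L artery, with non-overlapping groups in both (limma, adjusted p = 1 for each).

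**Figure D1:**
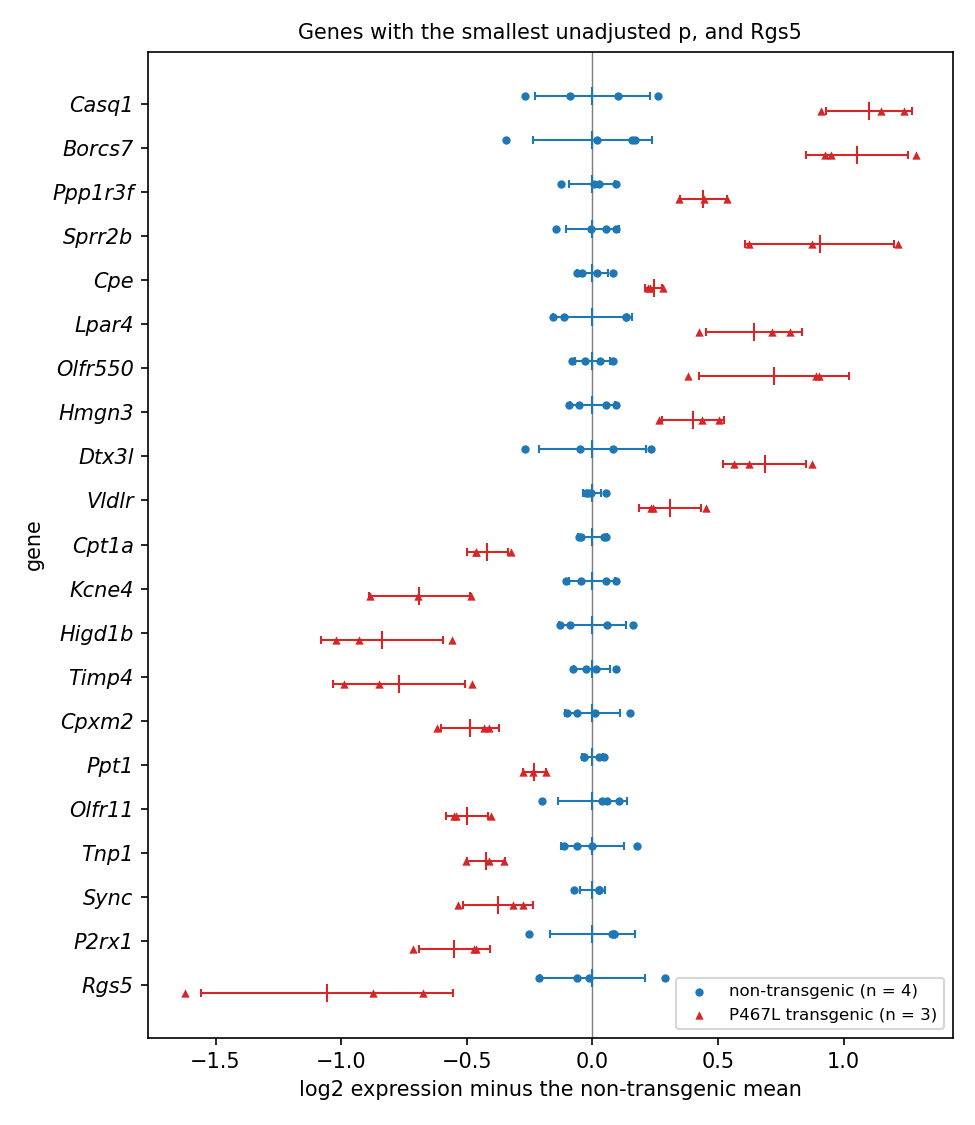
Log2 expression of each array minus the non-transgenic mean of that gene, for the 20 named genes with the smallest unadjusted p and for the brighter row of Rgs5. Circles are the 4 non-transgenic and triangles the 3 P467L arrays, and bars show mean ± SD; none of these genes passed the adjusted threshold, with the smallest adjusted p at 0.822 for Cpt1a.

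Groups of genes were compared next. Of 31 lists tested, 9 passed an adjusted p of 0.05 in camera, a test that compares a list with all other rows, at its preset correlation between genes of 0.01. The means of 7 lists were lower and those of 2 higher in P467L artery. With the correlation estimated from the arrays 0 lists passed, and the smallest adjusted p, shared by several lists, was 0.590. The exact two-sided permutation test of the list scores, whose smallest p is 0.0571, reached it for fatty acid oxidation genes, ion channels and brown fat markers, of which the last did not pass in camera (adjusted p = 0.125). For the other lists that passed, the exact permutation p was 0.114 for contractile, 0.171 for matrix, 0.229 for PPAR target, 0.229 for fibroblast, 0.400 for adipocyte, 0.514 for macrophage and 0.571 for oxidative phosphorylation genes. In fry, which asks whether the genes of a list move one way without reference to other genes, 0 lists passed and the smallest adjusted p was 0.795.

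The lists of PPAR target, fatty acid oxidation and oxidative phosphorylation genes were lower in P467L artery. Of 34 measured PPAR target genes 27 had lower and 7 higher means, with a median difference of -0.11 (camera, adjusted p = 0.000256; adjusted p = 0.590 with an estimated correlation). Over all rows 0 members passed, and 1, Cpt1a, passed when adjusted over the list alone. Ech1, an enzyme of peroxisomal and mitochondrial fat breakdown, had a 1.51-fold lower mean, and Pdk4, which turns off pyruvate oxidation when fat is burned, a 2.36-fold lower one. The adipocyte-type targets Fabp4 and Cd36 differed by -0.29 and -0.36, less than the SDs of 0.49 and 0.91 between non-transgenic mice. Fabp4 was at 7.95 in non-transgenic replicate 1 and from 6.80 to 7.13 on the other arrays. Of 22 fatty acid oxidation genes 19 had lower means, with a median of -0.084 (camera, adjusted p = 0.000256; adjusted p = 0.590 with an estimated correlation). In this list 0 members passed over all rows and 1 when adjusted over the list alone, again Cpt1a, and Acaa2 differed by -0.30. The list shares 6 measured genes with the PPAR targets. Its score, the mean log2 deviation of its genes, was -0.076 ± 0.0066 (SD, n = 3) against 0.057 ± 0.13 (SD, n = 4) with no overlap (exact permutation p = 0.0571, the smallest possible). Of 37 oxidative phosphorylation genes 30 had lower means, with a median of -0.087 (camera, adjusted p = 0.000305; adjusted p = 0.627 with an estimated correlation). Atp5b differed by -0.23 and Cox4i1, a subunit of cytochrome oxidase, by -0.16, and 0 members passed over all rows or when adjusted over the list alone. Its score was -0.17 in P467L replicate 3, the lowest of the 7 arrays, and 0.0099 and 0.0045 in P467L replicates 1 and 2.

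Markers of fat cells moved with these lists. Of 11 measured adipocyte markers 10 had lower means in P467L artery, with a median of -0.31 (camera, adjusted p = 0.0440; adjusted p = 0.765 with an estimated correlation) and 0 members past the threshold, over all rows or adjusted over the list alone. Plin1, which coats lipid droplets, differed by -0.14 and Aqp7, a glycerol channel, by -0.24. Plin1 was at 6.90 in P467L replicate 2 and from 7.13 to 7.43 on the other arrays. Aqp7 was at 6.34 in non-transgenic replicate 1 and from 5.53 to 5.87 on the other arrays. The fat hormone gene Adipoq was at 10.69 in non-transgenic replicate 1 and between 8.45 and 9.62 on the other arrays. With the adipocyte score as a covariate the median of the PPAR targets was -0.0086 (camera, adjusted p = 0.160). The calls of fatty acid oxidation (median -0.021, adjusted p = 0.147) and oxidative phosphorylation (-0.034, 0.0825) also ended. That of adipocyte markers (0.015, 0.960) had to end, because the covariate is made from the same markers, so its end tells nothing. Without non-transgenic replicate 1 the medians were -0.033 for PPAR targets, -0.028 for fatty acid oxidation and -0.040 for oxidative phosphorylation, each at an adjusted p of 0.0260, while the adipocyte median was -0.043 and its call ended (0.343). Leaving out P467L replicate 1, P467L replicate 2, P467L replicate 3 or non-transgenic replicate 4 also ended the adipocyte call, with adjusted p of 0.392, 0.112, 0.0594 and 0.141 and medians of -0.17, -0.37, -0.27 and -0.32. Without P467L replicate 3 the oxidative phosphorylation median was -0.040 and its call ended (0.0594), as it did with array weights (-0.011, 0.145).

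Contractile genes of smooth muscle were lower in P467L artery, by a small amount. Of 25 measured members 21 had lower means, with a median of -0.097 and a mean of -0.11 (camera, adjusted p = 7.86e-05; adjusted p = 0.590 with an estimated correlation), and 0 passed over all rows or when adjusted over the list alone. Des, the intermediate filament desmin, differed by -0.28 with non-overlapping groups, and Myocd, the transcription factor that drives the contractile program, by -0.40. Mrvi1, a target of cGMP-dependent kinase, differed by -0.17, whereas the abundant Acta2 and Tagln differed by -0.034 and -0.062. Of 41 vascular ion channel genes 26 had lower and 14 higher means, with a median of -0.0325 (camera, adjusted p = 0.0329; adjusted p = 0.590 with an estimated correlation, unadjusted 0.0318). The scores of the 2 groups did not overlap (exact permutation p = 0.0571). Kcne4 was the 1 channel gene that passed when adjusted over the list alone, against 0 over all rows. Slc8a1, the sodium-calcium exchanger, differed by -0.34 and Kcnma1, the large-conductance potassium channel, by -0.26. The channel call ended without non-transgenic replicate 2 (adjusted p = 0.116) or 3 (0.107), without P467L replicate 1 (0.145), 2 (0.0621) or 3 (0.0618), with medians of -0.047 to -0.0225, and after a further quantile normalization (-0.016, 0.0582). The call was kept with medians of -0.016 with array weights, -0.056 with the adipocyte score as a covariate, -0.057 with the lowest 50% of rows left out and -0.087 with tied rows left out.

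Genes of the extracellular matrix were lower in P467L artery while markers of fibroblasts, which make much of that matrix, were higher. Of 44 matrix genes 29 had lower and 13 higher means, with a median of -0.051 (camera, adjusted p = 0.000450; adjusted p = 0.590 with an estimated correlation). The 1 member that passed when adjusted over the list alone was Timp4, against 0 over all rows. The collagen genes Col12a1 and Col6a3 differed by -0.67 and -0.40. The matrix score was -0.18 in P467L replicate 3, the lowest of the 7 arrays, and 0.0038 and 0.0072 in P467L replicates 1 and 2. The median was -0.085 without P467L replicate 1, and without P467L replicate 3 it was -0.028 and the call ended (adjusted p = 0.206), as it did with array weights (-0.026, 0.181), while with tied rows left out the median was -0.092. Of 14 fibroblast markers 13 had higher means, with a median of 0.14 (camera, adjusted p = 0.000380; adjusted p = 0.627 with an estimated correlation). Dcn, the proteoglycan decorin, was at 11.47 ± 0.08 (SD, n = 3) against 11.20 ± 0.18 (SD, n = 4) with no overlap, and Dpep1 differed by 0.23. Of 15 macrophage markers 14 had higher means, with a median of 0.14 (camera, adjusted p = 0.000450; adjusted p = 0.590 with an estimated correlation). Aif1, which codes for the macrophage protein IBA1, differed by 0.35, the chemokine receptor gene Cx3cr1 by 0.36 and Adgre1, a macrophage surface receptor gene, by 0.16. The macrophage score was 0.090, 0.34 and -0.17 in P467L replicates 1, 2 and 3, the highest and the lowest of the 7 arrays being P467L replicates 2 and 3, which also end the first principal component. In the fibroblast and macrophage lists 0 members passed over all rows or when adjusted over the list alone. Without P467L replicate 2 both calls ended, with a median of 0.086 and an adjusted p of 0.0998 for fibroblast and of 0.058 and 0.240 for macrophage markers. The fibroblast median was 0.092 without non-transgenic replicate 2 and 0.265 without P467L replicate 3, and the macrophage median was 0.24 without non-transgenic replicate 1 and 0.27 without P467L replicate 3, and 0.215 with the lowest 50% of rows left out.

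**Figure D2:**
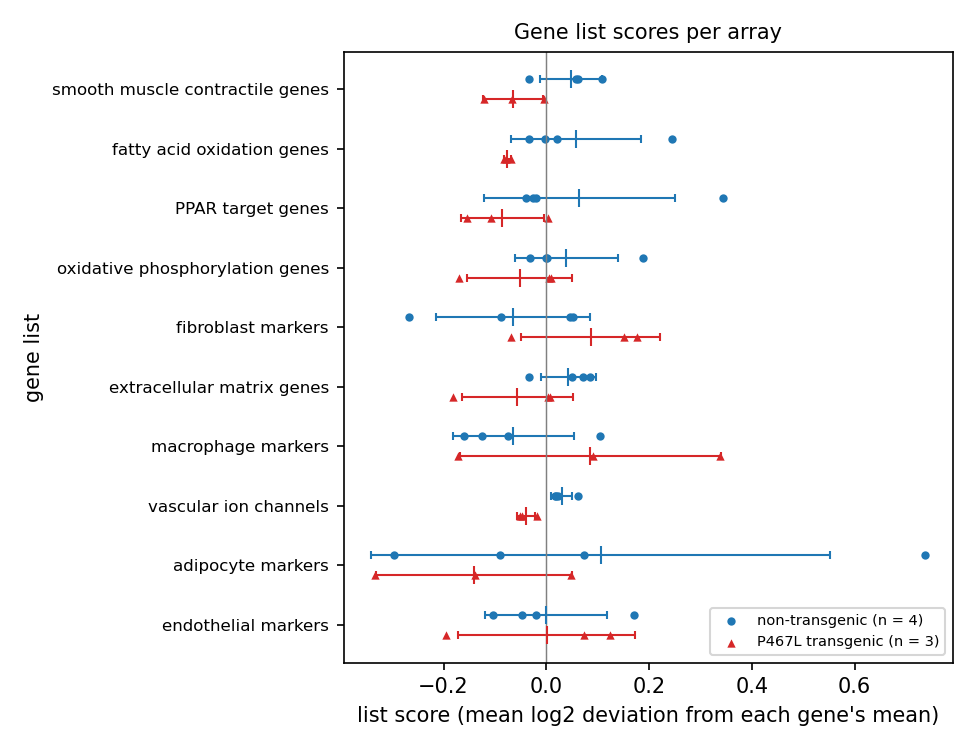
Score per array, the mean log2 deviation of a list's genes from their means over the 7 arrays, for the 9 lists past the threshold in camera and for endothelial markers. Circles are the 4 non-transgenic and triangles the 3 P467L arrays, bars show mean ± SD, and only the scores of fatty acid oxidation genes and vascular ion channels, of the lists drawn, have no overlap between the groups.

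Other lists tied to vascular tone and PPARγ did not pass. The 20 RGS genes, brakes on G protein signalling, had a median difference of 0.013 and a mean of -0.033 (camera, adjusted p = 0.873), with 11 members higher and 8 lower, Rgs17 at 0.26 and Rgs4 at -0.49 beside Rgs5. Rgs4 was at 8.04 in P467L replicate 3 and from 8.72 to 9.18 on the other arrays. The 34 vasoactive receptor and nitric oxide genes had a median of -0.012 (adjusted p = 0.275), among them the vasopressin receptor gene Avpr1a at -0.31 and the endothelin receptor gene Ednrb at -0.41. The 15 circadian clock genes had a median of -0.075 (adjusted p = 0.0789), with Arntl, the core clock activator, at 0.17 and Nr1d2 at -0.24. Single arrays weigh on both differences. Arntl was at 5.84 in non-transgenic replicate 4 and from 6.28 to 6.75 on the other arrays. Nr1d2 was at 8.49 in P467L replicate 3 and from 8.71 to 9.05 on the other arrays. The 20 endothelial markers had a median of -0.00042 and a mean of 0.0013 (adjusted p = 0.885), with the connexin gene Gja4 at -0.24. The endothelial list passed as higher with array weights (median 0.084, adjusted p = 0.0182) and without P467L replicate 3 (0.077, 0.0391), the circadian list passed as lower without P467L replicate 2 (-0.14, 0.0190), with array weights (0.0487) and with the lowest 50% of rows left out (0.0459), and the vasoactive list in the last of these (0.0457). With 1 array left out the circadian median ran from -0.14 to -0.0175 (without P467L replicate 3), and the vasoactive median from -0.047 (without non-transgenic replicate 3) to 0.0033 (without non-transgenic replicate 1). In each of these lists 0 members passed over all rows or when adjusted over the list alone.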

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

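The tests of the fibroblast minus endothelial score, of single arrays behind the contractile, fibroblast and macrophage lists, of the splits for single lists and for few rows, and of tied rows were chosen only after the results were seen. A gap ratio, the distance of the highest or lowest of the 4 non-transgenic arrays from its nearest neighbour divided by their range, was above Dixon's 95% critical value for 21 of 153 results; chance puts about 1 in 20 there, genes share arrays, and ties raise the ratio. P467L arrays, a group of 3, were not tested.

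Among scores, non-transgenic replicate 1 stood high for PPAR target genes (gap ratio 0.945, score 0.34 against a mean of -0.029 on the other 3) and for oxidative phosphorylation genes (0.853, 0.19 against -0.011). Non-transgenic replicate 2 stood high for vascular ion channels (0.885, 0.061 against 0.019), and non-transgenic replicate 4 for brown fat markers (0.857).

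Among genes, non-transgenic replicate 1 stood high for Egr2 (gap ratio 1, 7.72 on this array) and Krt18 (1, 7.45 against 7.43), and low for Msln (1) and Prss2 (1). Non-transgenic replicate 2 stood high for Ppp1r14a (0.897) and Kcnma1 (0.848), and low for Gbp3 (0.971, 7.03 against 7.37), Pdpn (0.941), Reln (0.933) and Thy1 (0.976, 7.23 against 7.64). Non-transgenic replicate 3 stood low for Sync (1, 8.03 against 8.13) and Pdk1 (0.947), and high for Cd5 (1). Non-transgenic replicate 4 stood low for P2rx1 (0.971, 8.82 against 9.16), and high for Dbp (0.947), Gja4 (0.962, 8.94 against 8.68) and Tnni2 (1).

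The first pattern is the lower PPAR target and fatty acid oxidation lists. Chance is not excluded for either list: 2 of the 35 splits gave the PPAR targets a camera p as small (unadjusted 2.48e-05 against 1.22e-05 in the other split). For the fatty acid oxidation genes 2 of the 35 did so (1.86e-05 against 3.13e-06). The real split gave the most lists, 9, with 8 in the highest other. The 34 other splits gave a median of 4 lists, so camera at the preset correlation also called lists in groupings other than genotype. Among other lists that passed, the splits with a camera p as small numbered 11 of 35 for adipocyte and 5 for fibroblast markers. They numbered 4 for matrix, 4 for oxidative phosphorylation, 3 for macrophage and 2 for channel genes. More fat on the non-transgenic vessels stays open, since the PPAR median went to -0.0086 with the adipocyte score as a covariate and to -0.033 without non-transgenic replicate 1, where the call was kept. The PPAR and adipocyte lists share 0 measured genes, and Cpt1a kept a difference of -0.40 with the covariate. In P467L replicate 2 Adipoq (9.62) was above 3 of 4 non-transgenic arrays and the fatty acid oxidation score (-0.069) was below all of them. The PPAR target score on that array (0.0034) followed Adipoq, above non-transgenic replicates 2, 3 and 4 (-0.040, -0.027 and -0.019). The adipocyte list score there (0.048) was above non-transgenic replicates 2 and 3 (-0.30 and -0.090) and below replicates 1 and 4 (0.74 and 0.073). An effect of the transgene in smooth muscle remains a hypothesis that cannot be told apart from fat here, because without non-transgenic replicate 1 the mean difference went from -0.15 to -0.057 for PPAR targets and from -0.25 to -0.037 for adipocyte markers; for fatty acid oxidation genes it went from -0.13 to -0.071, with the P467L scores still below all others, but that call too ended with the adipocyte score (adjusted p = 0.147).

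The second pattern is the lower contractile list with higher fibroblast and macrophage lists. A smaller share of smooth muscle would raise endothelial markers too; the fibroblast minus endothelial score differed by 0.15 between the groups (exact two-sided permutation p = 0.229), which decides neither way. The test with the first residual component, under which 3 of the 3 lists kept their calls, is void, since that component is uncorrelated with genotype by construction. For the fibroblast and macrophage lists 1 array, P467L replicate 2, may carry the call, as the adjusted p of the fibroblast list was 0.0998 without it, and the abundant macrophage transcript Tyrobp was at 8.92 there and at 7.49 in P467L replicate 3. For the contractile list no single array does, with an adjusted p of at most 0.00214, but chance is not excluded: 2 of the 35 splits gave a p as small, with adjusted p of 7.86e-05 for the real one and 2.13e-07 for non-transgenic replicates 1, 2 and 3 against the other 4 arrays.

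The third pattern is the shortfall of rows at an unadjusted p under 0.05, 3.10% where chance gives 5%. Rows tied on 4 or more arrays explain little of it, since the share was 3.28% among the 18661 rows without such ties. The 95% exact interval, 3.03 to 3.55, takes rows as independent, which they are not, so it does not measure the uncertainty. Rows with fewer ties stayed in, as 10092 rows had 7 different values. Variation shared by arrays of both groups may widen the spread within groups: 9 of the 34 other splits gave more than 5% of the rows, up to 12.9% (3014 rows) for non-transgenic replicate 1 with P467L replicates 1 and 2, which points to a structure of the samples. Chance is not excluded for the shortfall, as 11 of the 35 splits gave 724 rows or fewer, down to 579, nor for a count as large, which 25 of the 35 splits gave. For the counts of 0 rows higher and 0 rows lower the count of splits is void: all 35 must reach 0, and no split gave more. No biological explanation of this structure was tested.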

How the results depend on the processing

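The alternatives with tied rows left out and with the first residual component were chosen after seeing the data. In every alternative run limma called 0 rows higher and 0 lower. The count at an unadjusted p under 0.05 was 354 with the lowest 50% of rows left out and 409 with rows of 1 symbol (fewer rows tested). It was 2834 with array weights, where P467L replicate 1 had most of the weight of its group (3.54). It was 1287 with the first residual component, which takes up variation within groups and is uncorrelated with genotype by construction. The causes of these higher counts were not tested further. With arrays left out the count was 611 to 1229, the upper end without P467L replicate 2 and 1145 without P467L replicate 3. The share of higher rows was 49.9%, and none of the scaling alternatives moved it by over 10 percentage points. The count of lists was 5 with the adipocyte score as a covariate, where the adipocyte call had to end. It was 0 with an estimated correlation and 0 in fry, both of which allow for correlated genes. With arrays left out it was 7 to 9, but 5 of the original 9 were kept without P467L replicate 2 or 3. Array weights kept 7, ending the matrix (median -0.026, adjusted p = 0.181) and oxidative phosphorylation (-0.011, 0.145) calls; tied rows left out ended the adipocyte call (median -0.33, 0.0594), and the first residual component ended it (-0.31, 0.0782) and the channel call (-0.0325, 0.0640), with medians not smaller than reported. The contractile list was kept in every alternative with the preset correlation. Among these, trended robust moderation does not reach camera and could not change the call. The Pparg difference was 0.053 with the adipocyte score and ran from -0.21 to 0.027 with arrays left out.

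Of 2090 values of named genes under alternatives 16 reversed and 2074 kept direction and side, none of them past the threshold. The cause of the reversals was not tested. Many values could not reverse: row filters, trended robust moderation and the first residual component leave a gene's difference unchanged. Genes with non-overlapping groups also keep their direction when 1 array is left out. Trended robust moderation was not passed to camera, so list values under it equal the reported ones and count as kept. Cul3 was at 0.016 after quantile normalization, 0.011 with array weights and 0.080 with the adipocyte score, where Cd36 was at 0.16. With array weights Krt18 was at 0.029 and Uchl1 at 0.014. With arrays left out the ranges were -0.12 to 0.077 for Cul3, -0.79 to 0.073 for Cd36, -0.15 to 0.26 for Alas2, -0.56 to 0.18 for Cd79a, -0.82 to 0.10 for Hsph1, -0.75 to 0.19 for Hspa1a and -0.083 to 0.098 for Slc4a1. Of 534 values of the reported lists 460 kept the direction and side of camera, 25 lost and 9 gained a call, and 40 turned direction, all in lists that did not pass as reported; 71 medians changed sign or moved to or from 0. Their medians were -0.0025 for redox, -0.0033 for cholesterol synthesis and -0.027 for mesothelial genes with the lowest 50% of rows left out, and 0.094 for heat shock, 0.018 for cholesterol synthesis and 0.043 for ribosomal genes with array weights. With the adipocyte score they were 0.018 for cholesterol synthesis, 0.099 for ribosomal, -0.020 for mesothelial and 0.0064 for skeletal muscle genes, with the replicate block 0 for glycolysis and -0.028 for endothelial genes, with tied rows left out 0.013 for redox genes, and with the first residual component -0.013 for intestinal and pancreatic genes. With arrays left out the ranges were -0.037 to 0 for cholesterol synthesis, -0.11 to 0.097 for ribosomal, -0.035 to 0.0875 for mesothelial, -0.0083 to 0.024 for skeletal muscle, -0.0083 to 0.028 for redox, -0.040 to 0.0775 for endothelial, -0.0375 to 0.0025 for intestinal and pancreatic, -0.020 to 0.0067 for glycolysis, -0.015 to 0.0175 for cell cycle, -0.015 to 0.025 for RGS, -0.18 to 0.175 for heat shock, 0.030 to 0.095 for T cell, 0 to 0.065 for B cell and -0.019 to 0.040 for Schwann cell and neuron genes. The heat shock list alone passed in its turned direction, without P467L replicate 3.

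Whether the replicate numbers pair the mice is not known here. Deviations of same-numbered arrays correlated at 0.116, -0.205 and -0.0904, and 1 of 3 P467L arrays correlated best with its own number. These values gave no sign of pairing, but so few pairs cannot exclude it. With the replicate block, in which non-transgenic replicate 4 has no partner, 914 rows had an unadjusted p under 0.05, 8 lists passed (the adipocyte call ended, adjusted p = 0.240) and Pparg differed by -0.13. Signal over background cannot be judged without detection calls, so differences of dim rows are the least certain.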

Other observations

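The neighbour test was planned before its result was seen. Lists of the remaining cell types and pathways were tested with camera on the same fit, and none of the following passed. Among immune cells, T cell markers had a median difference of 0.042 (adjusted p = 0.242), B cell markers 0.0125 (0.325), and mast cell and neutrophil markers 0.018 (0.127), with Fcer1a, a chain of the IgE receptor, at 0.48 (adjusted p = 1) and non-overlapping groups. Fcer1a was dim, at 3.42 in non-transgenic and 3.90 in P467L artery. Without P467L replicate 2 the 3 immune cell lists passed, with medians of 0.095, 0.065 and 0.050 and adjusted p of 0.0114, 0.0403 and 0.0118. Of 8 brown fat markers 7 had lower means, with a median of -0.11 (0.125) and non-overlapping scores (exact permutation p = 0.0571), led by Ppargc1a, a coactivator of mitochondrial genes, at -0.28. Ppargc1a was at 6.58 in P467L replicate 2 and from 7.02 to 7.28 on the other arrays. The brown fat median was -0.041 without P467L replicate 2 (adjusted p = 0.509) and -0.035 with array weights (0.203), and the score of P467L replicate 3 was 0.0079, just below the lowest non-transgenic score of 0.010. Schwann cell and neuron markers (median -0.0042, mean 0.032, 0.629), mesothelial (0.0037, 0.873), skeletal muscle (0.0021, 0.885) and intestinal and pancreatic markers (-0.013, 0.873) had medians close to 0. Lymphatic endothelial and red cell markers, with 4 and 3 measured genes, had medians of 0.157 and 0.066 and were too few to test.

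Among pathways, inflammation and NF-kappaB genes had a median of 0.021 (adjusted p = 0.382) and interferon response genes 0.010 (0.314), with Ifit2 at 0.25. With 1 array left out the inflammation median ran from -0.0075 (without P467L replicate 2) to 0.059 (without P467L replicate 3), and the interferon median from -0.0083 (without non-transgenic replicate 2) to 0.037 (without non-transgenic replicate 1). Redox genes had a median of 0.015 and a mean of -0.0052 (0.873): Nox4 and Gpx4, an NADPH oxidase and a peroxidase, differed by -0.46 and -0.45, and Cybb, the oxidase of phagocytes, by 0.37. The groups overlapped for Nox4, Gpx4 and Cybb. Gpx4 was dim, at 4.815 in non-transgenic and 4.36 in P467L artery, below the lower quartile of every array. Immediate early genes had a median of -0.050 (0.175; 0 without non-transgenic replicate 1 and -0.0875 without P467L replicate 2), heat shock and protein folding genes -0.017 (0.665), cholesterol synthesis -0.0050 (0.840), glycolysis 0 with a mean of 0.0085 (0.873, lower in the test), with Pfkp at -0.29, and cell cycle genes 0 (0.873). Ribosomal protein genes had a median of 0.023 and a mean of -0.056 (0.744), with Rps18 at -0.61 and Rpl37 at -0.44. Rpl37 was at 6.53 in non-transgenic replicate 4 and from 5.04 to 5.93 on the other arrays. Without P467L replicate 3, whose heat shock score was -0.50 against -0.17 to 0.28 on the other arrays, the heat shock list passed with a median of 0.175 (adjusted p = 0.0266).

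The smallest p of all rows belonged to a row without a gene symbol, ID 6867379. It was between 6.65 and 7.41 in the 4 non-transgenic mice and between 3.36 and 4.53 in the 3 P467L mice, a 9.85-fold lower mean with a difference of -3.30 and a standard error of 0.33 (limma, unadjusted p = 5.48e-05, adjusted p = 0.709). The second unnamed row with a lower mean, ID 4600275, differed by -1.34, and those with the smallest p among higher means, ID 4526565 and ID 5072007, by 0.65 and 1.06. These 4 rows had non-overlapping groups, and their genes are not known here. Whether any of them is a control row was not checked. ID 4526565 (4.34 in non-transgenic and 4.99 in P467L artery) and ID 5072007 (3.065 and 4.13) lay below the lower quartile of every array.

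A hypothesis was that sequence variants carried along with the inserted transgene might make low-p genes cluster on a chromosome. Among the 200 named genes with the smallest p, 16 pairs lay within 5 gene positions of each other, against a mean of 13.4 in 10000 random draws (one-sided permutation p = 0.267). The 95th percentile of the draws was 20 pairs. The bound set in advance, no more pairs than that percentile, excludes nothing, because a count above the mean meets it, so such clustering stays open.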
